A study of Mus musculus with 16 samples.

How the data were processed

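The study measured polyadenylated RNA of hepatocytes isolated in the presence of cycloheximide from mice on chow or on DDC diet for 4 weeks, as cytoplasmic RNA and as RNA of monosomes, light polysomes and heavy polysomes. There were 16 libraries, 2 for each of 8 groups of diet and fraction. Per the labels the chow fraction libraries came from preparations CH1_CH2 and CH3_CH4 and the DDC fraction libraries from preparations B and C, so that replicate numbers pair fractions within a diet and do not pair the diets. The chow cytoplasmic libraries carried the names CH1 and CH3 and the DDC cytoplasmic libraries the names C2 and D2. Whether numbers pair samples was checked once from the difference between replicates across genes: its correlation between fractions was 0.36 to 0.758 within chow, 0.306 to 0.37 between the DDC monosome, light and heavy polysome fractions, -0.05 to 0.165 between DDC cytoplasm and fractions, and -0.095 to 0.073 between diets.

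The submitters' processing notes name bcl2fastq 2.17.1.14, Trimmomatic, STAR 2.4.2a, Picard 1.119 and Cuffnorm, without options for Cuffnorm. The deposited values are FPKM per transcript scaled between libraries by Cuffnorm, although the file is named for counts: values were not whole, and for genes with a single transcript the lowest values times length fell on a common step in each library. The design assumed count-like values and gave a separate filter for FPKM, which was used. The step puts 1 fragment per kilobase at 0.0144 to 0.0781 FPKM. Since the values are scaled between libraries, sequenced depth cannot be read from this step. Summed FPKM ran from 375145 in cytoplasm to 1386166 on heavy polysomes, and 8313 to 9874 genes reached 1 FPKM in a library. Replicates had correlations of 0.95 to 0.985 across genes. CHOW monosome replicate 2 had the fewest genes with under 10 fragments (7.8 percent, against 15.3 to 33.6 in the others) and 1036 genes at 0 that its partner held.

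Transcripts were joined to genes with GENCODE M21 on GRCm38: 116728 of 117592 transcripts matched (99.27 percent), 93.9 percent with the same version, and the 864 without a match held at most 0.51 percent of a library's FPKM and were left out. FPKM were summed over the transcripts of each of 48158 genes. Genes with at least 1 FPKM in at least 2 libraries were kept, 11790 in all, of which 10861 are protein-coding. A gene below 1 FPKM in all chow libraries passes only through DDC. Lists with members that low in chow, such as the mitosis, fetal liver and marker lists, therefore lean towards rises among their tested members. A gene at 0 in both replicates of a group while at 100 FPKM or more elsewhere was treated as missing in that group, a choice made after the files had been seen, since abundant liver genes were listed so. This touched 37 genes in 108 gene and group pairs, and those genes were not tested singly in comparisons that use the group. In the fit to all 16 libraries the list tests camera and fry left all 37 out of each comparison. Counts and medians of a list can therefore include genes that its list test did not use. Genes that were off in a group meet the rule as well, so large diet differences can have been left untested. Sprr1a, for example, was at 0 in all chow libraries and at 177 to 899 FPKM in DDC. Alb was listed at 0 in all 16 libraries and is not analysed here.

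Values were log2(FPKM + 1). A linear model with 8 group means was fitted to all 16 libraries with limma 3.58.1 in R 4.3.3, with a mean-dependent variance trend, 8 residual degrees of freedom and 3.934 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 8 comparisons were DDC against chow in each of the 4 RNA pools, heavy polysomes against monosomes in each diet, and the difference between the diets of heavy polysomes against cytoplasm and of heavy polysomes against monosomes. The 29 gene lists were written out in advance and tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the 29 lists. Camera compares the list with all other genes, so its direction can differ from the sign of the list's median. The samples, comparisons, tests, filter and rule for naming genes were set before the data were examined, and so were the alternatives apart from those named below; the treatment of genes listed at 0 was not.

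Genes named in the text were the 5 largest rises and 5 largest falls among called genes with a group mean of at least 100 FPKM and replicates that did not overlap, leaving out predicted genes, then 12 fixed genes (Alb, Cyp7a1, Alas1, Fech, Krt19, Spp1, Sox9, Ccnd1, Mki67, Atf4, Malat1 and Hbb-bs), then the 3 members with the lowest p in the direction of each list that passed and of the ductal, replication, mitosis and ribosomal protein lists. Among the fixed genes, Malat1 and Hbb-bs were not called by limma (Benjamini-Hochberg) between the diets in cytoplasm (adjusted p = 0.732 and 0.422) or on heavy polysomes (0.454 and 0.757). Genes first named for cytoplasm, heavy polysomes and the chow contrast were used for the remaining comparisons of each kind. Some genes that this rule names are not reported here. Genes with near-identical copies (Mup, Gst, Serpina and ribosomal protein genes) have uncertain shares.

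Alternatives were pseudocounts of 0.5 and 5, no filter, a filter at 50 FPKM, TMM scaling, quantile normalization, scaling to equal totals, a fit to the compared groups alone, array weights, transcript values, leaving out each replicate in turn, a replicate block, and light in place of heavy polysomes. Alternatives chosen after seeing the data were listed zeros kept as values, genes at 0 in a whole group left out, equal totals for the lists, and a fit without the 4 chow libraries of preparation 1. The model was tested on simulated data of the same size with 100 genes changed by 1 and 100 by 2 log2 units. Libraries were independent, each gene had 1 spread in all groups, and changed genes had a mean log2 value above 2. The rates therefore do not cover lower genes or the uneven spread and shared preparations of these data. Of genes changed by 2 log2 units, 82 percent were recovered for the cytoplasmic diet comparison and 90 percent for the chow contrast of heavy polysomes and monosomes. For the 2 differences between diets 44 and 49 percent were recovered. Of genes changed by 1 log2 unit the rates were 12, 15, 6 and 1 percent in the same order. Unchanged groups were simulated 20 times with heavy polysome values correlated with cytoplasmic values of the same replicate number as observed in each diet, a check added after the data had been seen. For sequence tests, a segment of 11 residues with a mean hydropathy of at least 2.2 in the first 40 residues was searched, and 5 genes matched on coding length and level were drawn for each gene in 10000 random sets. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.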

Results

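Hepatocyte RNA was compared between mice fed chow and mice fed DDC for 4 weeks, in cytoplasm and in 3 sucrose gradient fractions: monosomes (1 ribosome), light polysomes (2 to 4) and heavy polysomes (more than 5). The 8 comparisons ask which messages differed with the diet in each RNA pool, which messages were on heavy polysomes rather than monosomes in each diet, and whether the diet changed that placement. Each group held 2 libraries, values are FPKM as mean ± SD (n = 2), and the labels do not say that each library came from a separate animal. P-values therefore measure the spread between these samples, pooled over the 8 groups. That spread was uneven, with a replicate SD (log2) of 0.251 in DDC cytoplasm and 0.555 on chow heavy polysomes. Fractions of 1 preparation were treated as independent. Changes are on the scale of log2(FPKM + 1), which understates the change of genes with low values. Adjusted p-values are from limma with the Benjamini-Hochberg method unless another test is named, and coordinates are GRCm38.

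The first comparison asked which transcripts differed with DDC in cytoplasmic RNA. Ly6d (chromosome 15, 74762056 to 74763620), a surface protein of epithelial progenitors, was at 2070 ± 429 FPKM in DDC and 0.376 ± 0.0545 in chow, a log2 change of 10.54 (adjusted p = 0.000231). Lcn2 (chromosome 2, 32384633 to 32388252), an iron-scavenging acute-phase protein made by injured hepatocytes, was at 4252 ± 969 against 2.89 ± 2.98 (10.32, adjusted p = 0.000128). The protease inhibitor gene Slpi rose by 8.21, the calcium-binding protein gene S100a11 (chromosome 3, 93520488 to 93526287) by 7.64 (391 ± 35.3 against 0.955 ± 0.0762) and the interferon-inducible gene Ifi27l2b by 7.54. The largest falls were in genes for major urinary proteins, pheromone carriers secreted by the liver: Mup10 fell from 2632 ± 934 to 0.0555 ± 0.00449 FPKM (-11.24, adjusted p = 3.56e-06). Mup17 (-10.41) and Mup2 (-7.91) followed, although near-identical copies make the share of each Mup gene uncertain. Sult2a8 (chromosome 7, 14410686 to 14446769), a bile acid sulfotransferase gene, fell by 7.88 (305 ± 135 to 0.236 ± 0.111). The organic anion transporter gene Slco1a1 (chromosome 6, 141907282 to 141946962) fell by 6.47. Among genes listed in advance, Cyp7a1, the first enzyme of bile acid synthesis, fell by 2.96 (adjusted p = 0.00582). Fech, the last enzyme of heme synthesis, fell by 1.17 (0.0105). Alas1, the first enzyme of that pathway, was not called (188 ± 45.3 against 202 ± 13.4, -0.12, adjusted p = 0.872).

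**Figure D1:**
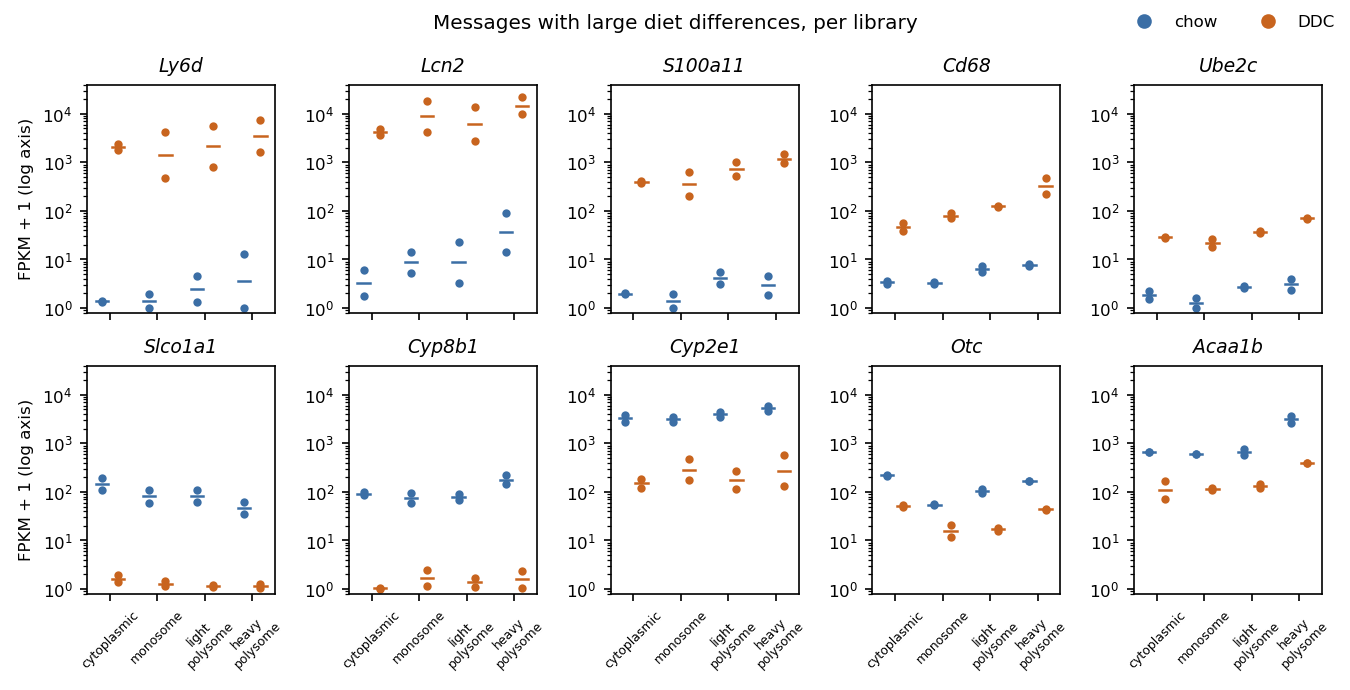
Named genes with large diet differences; points are single libraries and bars geometric means of FPKM + 1, on a log axis, with chow in blue and DDC in orange. In each RNA pool Ly6d, Lcn2, S100a11, Cd68 and Ube2c lie higher in DDC, and the 5 metabolic and transport genes lie lower.

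In cytoplasmic RNA 5 lists of metabolic genes fell. Of 30 fatty acid oxidation and ketogenesis genes 23 fell and 0 rose (28 fell when adjusted over the list alone; median -1.31). The peroxisomal thiolase gene Acaa1b fell by 2.62 (660 ± 14.7 to 116 ± 66.7). Of 37 urea cycle and amino acid catabolism genes 20 fell and 0 rose (29 fell over the list alone; median -1.33). They included Otc of the urea cycle (220 ± 6.81 to 50.6 ± 2.64) and Tdo2 of tryptophan breakdown (442 ± 140 to 41.1 ± 5.58). Of 29 genes of bile acid synthesis and transport 16 fell and 2 rose (17 and 2 over the list alone). Cyp8b1 (chromosome 9, 121914356 to 121916305), which sets the cholic acid share, fell by 6.49 (91.5 ± 7.24 to 0.0304 ± 0.013). Of 38 cytochrome P450 genes 12 fell and 1 rose (13 and 1 over the list alone), with Cyp2e1 at -4.42 (3293 ± 788 to 154 ± 44.6). Of 75 nuclear oxidative phosphorylation genes 40 fell and 0 rose (46 fell over the list alone), among them the ATP synthase gene Atp5g3 at -1.33. These 5 lists passed camera, a test of whether a list ranks above or below the other genes, with a preset correlation of 0.01 (adjusted p = 6.13e-15, 5.91e-12, 1.85e-05, 0.000695 and 1.53e-14 in the order given). None of these 5 calls held with the correlation between genes estimated from the libraries (adjusted p = 0.056, 0.207, 0.207, 0.252 and 0.252 with an estimated correlation).

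In the same pool 7 lists rose, apart from 3 of markers of other cell types. Of 33 mitosis genes 29 rose and 0 fell (31 rose over the list alone; median 1.91). Ube2c (chromosome 2, 164769898 to 164778822), the ubiquitin-conjugating enzyme of the anaphase-promoting complex, went from 0.877 ± 0.495 to 27.6 ± 0.421. Prc1, which bundles spindle microtubules, rose by 3.18 (adjusted p = 5.01e-06). Of 36 DNA replication genes 25 rose and 0 fell (28 rose and 2 fell over the list alone), including Uhrf1 and the ribonucleotide reductase gene Rrm2 (19.4 ± 1.25 against 1.83 ± 0.657). The proliferation marker Mki67 stood at 3.92 ± 0.984 against 0.0423 ± 0.00163. Cyclin D1 (Ccnd1) was at 88.2 ± 6.48 against 19.4 ± 15.9 (2.39, adjusted p = 0.0249). Of 40 cytokeratin and cytoskeleton genes 33 rose and 0 fell (36 rose over the list alone). The keratin gene Krt8 (chromosome 15, 101996698 to 102004482) was at 995 ± 234 against 53.7 ± 4.46. Of 32 NRF2 and glutathione genes 17 rose and 0 fell (19 rose over the list alone), led by Gsta1 (229 ± 100 against 3.35 ± 0.529) and the sulfiredoxin gene Srxn1. In the fetal liver and progenitor list 8 of the 9 genes tested rose (8 over the list alone), with the imprinted RNA H19 at 29.6 ± 9.95 against 0.0312 ± 0.0049. The list's other members were not tested, and a member as low in chow as H19 passed the filter only through DDC. Of 26 acute-phase genes 12 rose and 1 fell (14 and 1 over the list alone; Lrg1 at 1322 ± 35 against 141 ± 26.8). Of 24 cholesterol synthesis genes 9 rose and 1 fell (10 and 1 over the list alone; Nsdhl at 1.84). By camera the adjusted p-values were 2.14e-23 for mitosis, 3.3e-11 for replication, 3.26e-17 for cytoskeleton, 5.74e-09 for NRF2, 6.4e-07 for fetal genes, 0.000567 for acute phase and 0.00374 for cholesterol synthesis. Mitosis and cytoskeleton also passed with an estimated correlation (adjusted p = 0.0189 each), whereas replication (0.056), NRF2 (0.0762), fetal genes (0.0846), acute phase (0.346) and cholesterol synthesis (0.435) did not.

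Ductal, macrophage and stellate markers rose alongside these groups in the hepatocyte preparations, and the other 4 marker lists did not pass. Of 16 cholangiocyte and ductal markers 11 rose and 0 fell (12 over the list alone). Osteopontin (Spp1) was at 85.5 ± 25.9 against 0.575 ± 0.141. The ductal transcription factor gene Sox9 rose by 1.36 and Tm4sf4 by 2.69, while Krt19 was not tested, since it reached 1 FPKM in 1 library alone (1.25 in DDC heavy polysome replicate 2). Of 25 Kupffer cell and macrophage markers 15 rose and 0 fell (16 over the list alone). Cd68 (chromosome 11, 69664213 to 69666153) was at 47 ± 12.7 against 2.38 ± 0.406 and Lyz2 at 228 ± 40.5 against 14 ± 2.02. Of 23 stellate cell and fibroblast markers 14 rose and 1 fell (20 and 1 over the list alone), including the proteoglycan gene Bgn (55.2 ± 0.158 against 12 ± 3.55). Timp1 was listed at 0 in both chow libraries and at 9.65 and 6.98 FPKM in DDC. The camera adjusted p-values were 3.72e-08 for ductal, 3.79e-09 for macrophage and 3.79e-09 for stellate markers, and with an estimated correlation 0.0583, 0.0811 and 0.0189.

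Several lists did not pass in cytoplasmic RNA. Of 79 cytosolic ribosomal protein genes 2 rose and 5 fell (1 and 4 over the list alone; median -0.04, adjusted p = 0.47), although Rpl10 fell by 1.22 and Rps27 by 1.17. Of 36 secreted plasma protein genes 1 rose and 3 fell (adjusted p = 0.353), and of 16 heme genes 1 rose and 2 fell (0.477). Of 34 integrated stress and unfolded protein response genes 2 rose and 1 fell (0.47) with Atf4 not called. Of 18 YAP and TEAD targets 5 rose and 1 fell (0.175, against 0.012 by fry, a rotation test of the list on its own that keeps the correlation between genes). Splicing regulators (44 genes, adjusted p = 0.875), proteasome genes (37 genes, 0.83), mitochondrially encoded messages (4 tested of 13, 0.83) were not called. Neutrophil (6 tested of 15, 0.108), lymphocyte (3 tested of 23, 0.174), endothelial (18, 0.935) and red blood cell markers (6 tested of 13, 0.894) were not either. The 50 translation factors (median 0.01, mean -0.03, adjusted p = 0.694) and 21 long noncoding RNAs (median -0.07, mean 0.07, 0.875) had medians and means of opposite sign.

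Over all 11767 genes tested in cytoplasmic RNA, 1492 were higher and 1137 lower with DDC (limma, Benjamini-Hochberg), 1178 and 736 of them by at least 2-fold. Without the 4 chow libraries of preparation 1, whose sex-linked genes differed from the rest, 969 genes were called, and the calls of Cyp7a1, Rpl10, Rps27 and Atp5g3 ended with their directions kept. Ccnd1 lost its call without a filter on low values (adjusted p = 0.068) and the cholesterol synthesis list without CHOW cytoplasmic replicate 2 (0.146). When each library was scaled to the same total the median of all genes moved by 0.17, so changes here are relative to the scaling of the deposited values.

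The fourth comparison asked which messages on heavy polysomes differed with DDC, that is, which sat on more than 5 ribosomes. S100a11 was at 1212 ± 359 FPKM in DDC and 2.28 ± 1.97 in chow (8.64, adjusted p = 2.2e-06). Cd63 (chromosome 10, 128900989 to 128912822), a tetraspanin of late endosomes, was at 549 ± 75.1 and 2.08 ± 0.671 (7.49, adjusted p = 7.67e-07). Lcn2 reached 15810 ± 8645 against 51.5 ± 53.7 (8.65), and Slpi rose by 8.53. Ly6d was at 1612 and 7274 FPKM in the DDC libraries against 11.7 and 0 in chow. Mup17 (-10.87) and Mup3 (-8.93) fell again, with wide chow values for Mup3 (4803 and 29000 FPKM). The carboxylesterase genes Ces3a (chromosome 8, 105048601 to 105058413) and Ces3b (chromosome 8, 105083753 to 105093929), which hydrolyse stored lipid and drugs, fell too (-7.81 and -6.77; Ces3b from 493 ± 31.5 to 3.63 ± 1.47). Cyp8b1 fell by 6.82 (183 ± 56.3 to 0.72 ± 0.944). Spp1 rose by 4.41 (adjusted p = 0.00318), and Sox9 was listed at 0 in both chow libraries against 0.764 and 0.664 FPKM in DDC. Cyp7a1 (-1.47, adjusted p = 0.108), Fech (-0.75, 0.0669), Alas1 (-0.55, 0.361), Ccnd1 (1.60, 0.108), Mki67 (0.37, 0.347) and Atf4 (-0.28, 0.486) were not called in this fraction. Ccnd1 was called without the 4 chow libraries of preparation 1 (2.37, adjusted p = 0.00697).

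On heavy polysomes 7 lists fell, 5 of which had also fallen in cytoplasm. Of 30 fatty acid oxidation genes 29 fell and 0 rose (29 over the list alone; median -1.48), with Acaa1b from 3173 ± 695 to 385 ± 1.97 and the isomerase gene Eci2 from 332 ± 8.41 to 86 ± 13.9. Of 75 oxidative phosphorylation genes 61 fell and 0 rose (70 over the list alone; median -1.18), including the complex I gene Ndufb8 (1692 ± 98.9 to 469 ± 119). Of 37 urea cycle and amino acid genes 13 fell and 0 rose (15 over the list alone), with Otc from 165 ± 2.02 to 43 ± 1.39. Bile acid genes (16 fell, 2 rose of 29; 18 and 3 over the list alone), cytochrome P450 genes (15 fell, 2 rose of 38) and secreted plasma protein genes (10 fell, 1 rose of 35; 12 and 1 over the list alone) fell too. Among them Pon1, a lipoprotein lactonase, went from 1111 ± 274 to 140 ± 82.6 and Apoh from 6530 ± 690 to 1933 ± 417. The secreted list lost its call under quantile normalization (adjusted p = 0.168). Proteasome genes fell in part (6 fell, 0 rose of 37; 6 over the list alone; median -0.31). Their median turned to 0.19 when libraries were scaled to the same total and the call ended there (adjusted p = 0.42). It ended under quantile normalization too (adjusted p = 0.857), and without DDC heavy polysome replicate 1 (0.0651). With equal totals the fatty acid oxidation and oxidative phosphorylation medians were -0.97 and -0.68, and the latter was -0.73 under quantile normalization. By camera the adjusted p-values were 1.29e-16, 9.39e-24, 1.13e-06, 3.51e-05, 9.85e-05, 9.85e-05 and 0.00297 in the order given. With an estimated correlation fatty acid oxidation passed (adjusted p = 0.0457) and the other 6 did not (0.156, 0.361, 0.193, 0.193, 0.382 and 0.382).

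On heavy polysomes 10 lists rose. Of 33 mitosis genes 26 rose and 0 fell (26 over the list alone), with Ube2c at 69.3 ± 1.97 against 2.2 ± 1.1. Racgap1, which directs cytokinesis, was at 7.22 ± 0.112 against 0.276 ± 0.117. Plk1 was listed at 0 in both chow libraries and at 8.51 and 5.91 in DDC. Of 36 replication genes 17 rose and 1 fell (25 and 1 over the list alone; Rrm2 at 25.6 ± 3.13 against 1.55 ± 0.183). Of 40 cytoskeleton genes 30 rose and 0 fell (34 over the list alone; Anxa5 at 527 ± 91.5 against 5.82 ± 3.32). Of 31 NRF2 genes 15 rose and 0 fell (17 over the list alone; Gsta1 at 649 ± 52.9 against 9.32 ± 4.67). Of 26 acute-phase genes 9 rose and 1 fell (11 and 2 over the list alone), and 7 of 9 fetal liver genes rose. Of 24 macrophage markers 18 rose and 0 fell (19 over the list alone; median 2.98; Cd68 at 351 ± 184 against 6.71 ± 0.544). Of 23 stellate markers 21 rose and 0 fell (21 over the list alone; Vim at 26.6 ± 0.761 against 0.371 ± 0.524). Of 16 ductal markers 12 rose and 1 fell (13 and 1 over the list alone; Tm4sf4 at 2.15). Of 18 endothelial markers 5 rose and 0 fell (6 over the list alone; Eng at 1.18), a call that ended without the 4 chow libraries of preparation 1 (adjusted p = 0.0771) or CHOW heavy polysome replicate 1 alone (0.0705). Camera gave adjusted p = 5.65e-18 for mitosis, 1.08e-06 for replication, 2.59e-15 for cytoskeleton, 5.5e-07 for NRF2, 0.0277 for acute phase, 7.3e-05 for fetal genes, and 1.76e-13, 2.32e-11, 4.73e-06 and 0.0138 for the 4 marker lists. With an estimated correlation mitosis (adjusted p = 0.0249), cytoskeleton (0.0249), macrophage (0.0457) and stellate markers (0.0249) passed, and replication (0.117), NRF2 (0.117), acute phase (0.48), fetal genes (0.172), ductal (0.117) and endothelial markers (0.193) did not. Ribosomal protein genes did not pass (median 0.23; 3 rose and 2 fell of 79; adjusted p = 0.2), although Rpl35 (1010 ± 58.1 against 478 ± 55.4), Rps16 and Rps12 rose.

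On heavy polysomes 1638 genes were higher and 1277 lower among 11764 tested (limma, Benjamini-Hochberg). Across genes the diet changes in heavy polysomes and cytoplasm had a correlation of 0.801, in which genes are not independent replicates. The 2 pools share preparations in chow. In 20 simulations of unchanged groups with the observed correlation of replicate deviations the correlation was 0.302 to 0.396, the covariance at most 0.063 (0.84 observed), and no gene was called in the same direction in both. Here 958 genes were higher in both (207 for independent lists), 604 lower in both (123) and 3 were called in opposite directions, and part of this agreement may come from the shared preparations. Without the 4 chow libraries of preparation 1 the calls of Spp1, Sox9, Apoh, Rpl35, Rps16, Rps12 and Eng ended. The acute-phase list lost its call without CHOW heavy polysome replicate 2 (adjusted p = 0.0778) or DDC heavy polysome replicate 2 (0.153). A fit to the heavy polysome libraries alone called 362 genes, and scaling to equal totals moved the median of all genes by 0.28.

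The comparisons in the lighter fractions asked the same of monosomes and light polysomes, for some of the genes and lists named above. The acute-phase and cytochrome P450 lists in these fractions are not reported here. Ribosomal protein messages fell on monosomes. Of 79 genes 66 fell and 0 rose (74 over the list alone; median -1.41; camera adjusted p = 1.76e-23, and 0.219 with an estimated correlation, against 0.000389 by fry), a median that went to -0.86 under quantile normalization. Rps27, of the small subunit, went from 5506 ± 22.7 to 1078 ± 108 and Rpl10, of the large subunit, from 2570 ± 24.7 to 656 ± 136. On light polysomes 13 of them fell and 2 rose (11 and 2 over the list alone; median -0.37; adjusted p = 0.0045, and 0.698 with an estimated correlation). That call ended under quantile normalization, where the median turned to 0.09 (adjusted p = 0.181), when libraries were scaled to the same total (adjusted p = 0.103) and without DDC light polysome replicate 1 (-0.06, adjusted p = 0.672), and the median was -0.68 without DDC light polysome replicate 2. Of 36 secreted plasma protein genes 16 rose and 5 fell on monosomes (16 and 5 over the list alone; median 0.70; adjusted p = 0.022, and 0.633 with an estimated correlation), among them the copper carrier gene Cp from 190 ± 9.16 to 1036 ± 91.2. The list's call ended without CHOW monosome replicate 2 (adjusted p = 0.0751) or DDC monosome replicate 1 (0.142). On light polysomes 6 of 32 fell and 0 rose (median -0.30; adjusted p = 0.0265, and 0.664 with an estimated correlation). The median turned to 0.11 under quantile normalization (adjusted p = 0.917) and to 0.03 with equal totals (0.0444), was -0.49 and -0.76 without CHOW or DDC light polysome replicate 2, and the call ended without CHOW light polysome replicate 1 (-0.16, adjusted p = 0.174), DDC light polysome replicate 1 (-0.07, 0.682) or the 4 chow libraries of preparation 1 (0.325). Fatty acid oxidation genes fell in both fractions (23 of 30 on monosomes and 26 on light polysomes; 25 and 27 over the list alone; camera adjusted p = 9.5e-12 and 3.16e-16, and 0.133 and 0.0547 with an estimated correlation). Acaa1b went from 607 ± 2.44 to 115 ± 7.26 and from 666 ± 118 to 131 ± 17.9. Mitosis genes rose in both (28 and 24 of 33; 30 and 27 over the list alone; camera adjusted p = 2.37e-12 and 2.09e-14, and 0.0749 and 0.0489 with an estimated correlation), with Ube2c at 4.12 and 3.75. Proteasome genes fell on light polysomes (14 of 37, 0 rose; adjusted p = 0.000723, and 0.328 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.163).

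Translation factors, not called in cytoplasm, fell on monosomes (18 fell and 5 rose of 50; adjusted p = 0.000667, and 0.166 with an estimated correlation). On light polysomes 13 fell and 2 rose (0.00237, and 0.184 with an estimated correlation), and the call ended under quantile normalization (adjusted p = 0.145). Cd68 rose by 4.62 and 4.27 and Krt8 by 4.28 and 4.46 in the 2 fractions, and Gsta1 by 5.64 and 5.12. Ces3b was at -5.68 and -6.36, while Mup10 and Mup17 were listed at 0 in the DDC libraries of both fractions and were not tested there. Macrophage markers (17 of 25 rose on monosomes, 16 rose and 1 fell on light polysomes; adjusted p = 8.41e-07 and 3.54e-07, and 0.167 and 0.181 with an estimated correlation) rose. Stellate markers did too (19 and 17 of 23 rose; adjusted p = 3.8e-10 and 1.46e-08, and 0.039 and 0.0441 with an estimated correlation). So did the cytoskeleton list (32 and 28 of 40; adjusted p = 2.37e-12 and 2.12e-13, and 0.0553 and 0.0441 with an estimated correlation). Of 75 oxidative phosphorylation genes 51 fell and 1 rose on monosomes (52 and 3 over the list alone) and 57 fell on light polysomes (62 over the list alone), with Ndufv2 of complex I from 246 ± 5.04 to 61.4 ± 10.1 on the latter (camera adjusted p = 2.37e-12 and 3.05e-20, and 0.321 and 0.185 with an estimated correlation). Replication (20 and 16 rose of 36), NRF2 (15 and 16 of 32), fetal (8 and 8 of 9) and ductal lists (11 and 11 of 16) rose in both fractions, and bile acid (14 and 17 fell of 29) and amino acid lists (12 and 16 fell of 37) fell. None of these 6 passed with an estimated correlation (adjusted p = 0.141 for ductal markers on light polysomes to 0.567 for amino acid genes on monosomes), and under quantile normalization the bile acid and amino acid calls on monosomes ended (0.0911 and 0.0673). Both calls also ended without DDC monosome replicate 2, where the bile acid median went from -0.88 to -0.60 (adjusted p = 0.126) and the amino acid median from -0.76 to -0.33 (0.197). On monosomes 2477 genes were higher and 1876 lower of 11767, and on light polysomes 1954 and 1587 of 11768 (limma, Benjamini-Hochberg). Scaling to equal totals moved the median of all genes by 0.25 and 0.23.

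**Figure D2:**
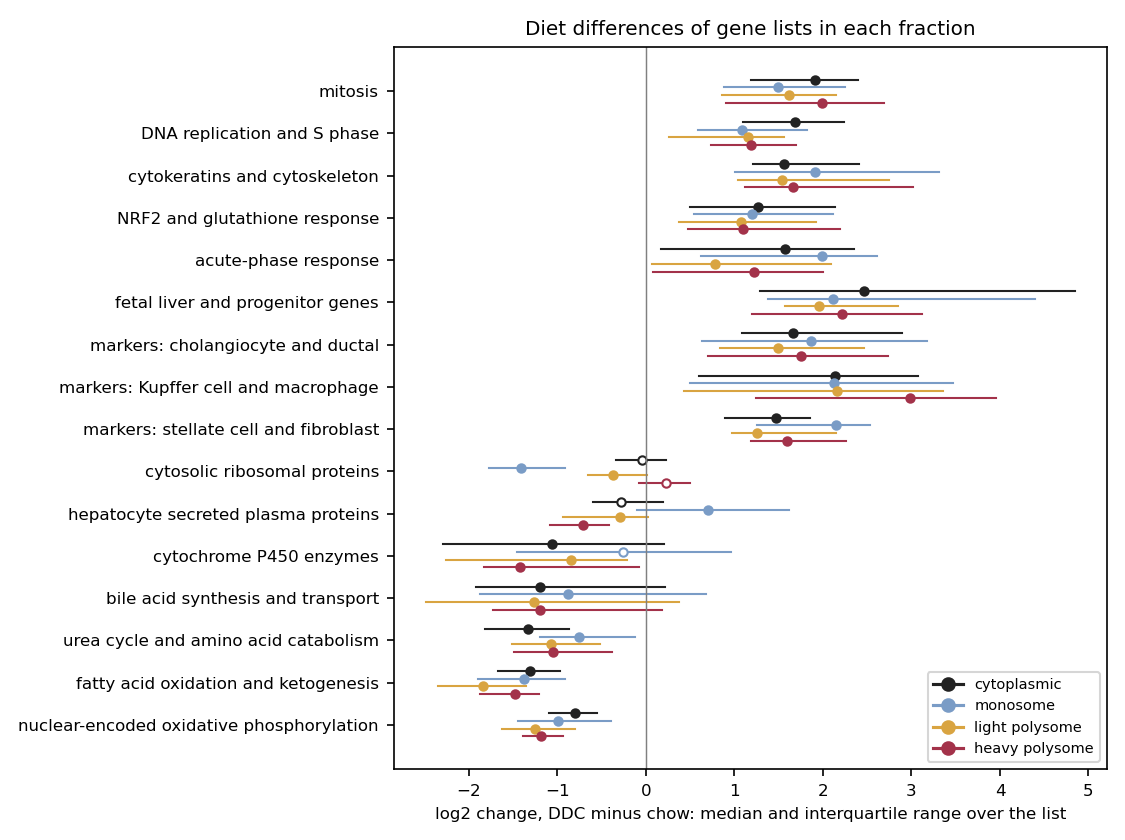
Median log2 change with DDC of each gene list in the 4 RNA pools; filled circles passed camera with the preset correlation and open circles did not. Ribosomal protein and secreted plasma protein lists differ between monosomes and heavy polysomes, while mitosis and fatty acid oxidation lists keep their side in all 4.

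The fifth comparison asked which messages sat on heavy polysomes rather than monosomes in chow hepatocytes. Nme1 (chromosome 11, 93956979 to 93968521), a nucleoside diphosphate kinase gene, was at 230 ± 38.9 FPKM on heavy polysomes and 13 ± 0.126 on monosomes (4.03, adjusted p = 1.18e-06). The glutathione transferase gene Gstt2 (chromosome 10, 75831114 to 75837424) was at 534 ± 86.9 and 22.5 ± 1.4. The acute-phase gene Orm2 (4.14) and the mitochondrial leucyl-tRNA synthetase gene Lars2 (4.42; 222 ± 199 against 7.39 ± 3.12) were higher too. The microRNA gene Mir6236 (6248 and 737 against 312 and 0 FPKM) was called, lost its call under quantile normalization (adjusted p = 0.0682) and turned to -0.78 when light polysomes took the place of heavy ones. Gas5 (chromosome 1, 161034422 to 161038539), a small nucleolar RNA host transcript with a short reading frame, was lower on heavy polysomes at 7.79 ± 2.29 against 349 ± 13.8 (-5.34, adjusted p = 1.18e-06). So were the host transcript Snhg8 (chromosome 3, 123507552 to 123508404; -4.48), Ccni (-4.12), Vti1b (-4.04) and Bola3 (-3.92). Atf4, whose upstream reading frames hold back translation without stress, was at 24.6 ± 6.21 on heavy polysomes and 119 ± 6.08 on monosomes (-2.25, adjusted p = 4.78e-05). Alas1 was at 532 ± 60.1 and 88.7 ± 36.5 (2.63, adjusted p = 0.000314). Cyp7a1 was lower on heavy polysomes (-2.43), and Fech, Ccnd1, Malat1 and Mki67 were not called (adjusted p = 0.736, 0.239, 0.79 and 0.932), although Ccnd1 was called as lower with the preparations as pairs (-1.04, adjusted p = 0.0109).

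All 37 proteasome genes were higher on heavy polysomes than on monosomes in chow (37 over the list alone; median 2.2, which was 1.37 under quantile normalization and 1.39 with equal totals), with the catalytic subunit gene Psmb5 (chromosome 14, 54614119 to 54618022) at 225 ± 11.1 against 16.4 ± 2.95. Of 36 secreted plasma protein genes 30 were higher and 2 lower (31 and 3 over the list alone). They included vitronectin (Vtn; chromosome 11, 78499091 to 78502324) at 10910 ± 2133 against 959 ± 124, and antithrombin (Serpinc1; chromosome 1, 160978585 to 161005863) at 4908 ± 1151 against 463 ± 96.4. Oxidative phosphorylation genes (54 higher, 3 lower of 75; 56 and 4 over the list alone; Ndufc2 at 446 ± 52.3 against 29.4 ± 5.22), and urea cycle and amino acid genes (21 higher, 0 lower of 37) lay the same way. So did fatty acid oxidation genes (21 higher, 3 lower of 30; 22 and 3 over the list alone; Etfb at 3.47), replication genes (17 higher, 0 lower of 36) and cytochrome P450 genes (13 higher, 0 lower of 38). NRF2 genes (14 higher, 4 lower of 32), heme genes (8 higher, 2 lower of 16; Alad at 3.06) and macrophage markers (11 higher, 1 lower of 24; C1qb at 2.68) were higher as well. Ribosomal protein genes lay the other way, with 57 of 79 lower on heavy polysomes and 2 higher (59 and 2 over the list alone; median -1.07, which was -1.78 under quantile normalization and -1.87 with equal totals). Rps12 (chromosome 10, 23785183 to 23787275) was at 397 ± 68.2 against 3099 ± 68. Of 21 long noncoding RNAs 13 were lower and 0 higher (14 over the list alone; Dleu2 at -4.27). By camera the adjusted p-values were 8.11e-18 for proteasome, 7.39e-07 for secreted proteins, 1.9e-14 for oxidative phosphorylation, 6.37e-06 for amino acid genes, 7.89e-06 for fatty acid oxidation and 0.0047 for replication. They were 0.0117 for cytochrome P450, 0.012 for NRF2, 0.0278 for heme, 0.019 for macrophage markers, 1.1e-12 for ribosomal proteins and 4.48e-06 for noncoding RNAs. With an estimated correlation the noncoding RNAs passed (adjusted p = 0.0416), and proteasome (0.0924), macrophage markers (0.603) and the other 9 lists (0.547 each) did not, while fry gave 0.00251 for ribosomal proteins. Under quantile normalization the calls of cytochrome P450 (adjusted p = 0.294), heme (0.152), amino acid (0.0682) and NRF2 genes (0.151) ended. With equal totals the lists higher on heavy polysomes kept their calls at lower medians. These went from 0.85 to 0.20 for NRF2 genes, 0.89 to 0.20 for macrophage markers and 0.80 to 0.19 for cytochrome P450 genes. Heme genes went from 1.13 to 0.37 and replication genes from 0.76 to 0.27. The macrophage call ended without CHOW monosome replicate 2 (0.081) or CHOW heavy polysome replicate 1 (0.0845), and the heme call without CHOW monosome replicate 1 (0.0697), CHOW heavy polysome replicate 1 (0.055) or the 4 chow libraries of preparation 1 (0.146).

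In the sixth comparison, the same contrast in DDC, Gas5 was again lower on heavy polysomes (8.02 ± 2.16 against 87.8 ± 0.623, -3.32) with Snhg8 (-2.97), Ccni (-3.37), Vti1b (-3.48) and Bola3 (-3.03). Nme1 was higher (320 ± 13.6 against 46.9 ± 3.51, 2.75). Atf4 was lower (-1.98, adjusted p = 0.000242) and Alas1 higher (1.35, adjusted p = 0.0245), the latter a call that ended under quantile normalization (adjusted p = 0.343). Mir6236, Lars2 and Orm2 were not called (adjusted p = 0.679, 0.125 and 0.306), although Orm2 was with the preparations as pairs (1.59, adjusted p = 0.0357). Of 37 proteasome genes 35 were higher and 0 lower (35 over the list alone; Psmb5 at 2.46). Of 75 oxidative phosphorylation genes 57 were higher and 2 lower (58 and 2 over the list alone), and of 30 fatty acid oxidation genes 18 were higher and 1 lower. Of 37 amino acid genes 19 were higher and 1 lower (24 and 1 over the list alone). Of 25 macrophage markers 18 were higher and 0 lower (C1qb at 1059 ± 3.06 against 119 ± 24.6). Of 33 mitosis genes 12 were higher and 1 lower (Cdc20 at 28.3 ± 0.669 against 5.47 ± 2.26). Of 21 long noncoding RNAs 12 were lower and 0 higher (15 over the list alone). Of 79 ribosomal protein genes 30 were higher and 8 lower (34 and 9 over the list alone; median 0.59; adjusted p = 0.000463, and 0.779 with an estimated correlation). The median turned to -0.11 under quantile normalization (adjusted p = 0.0464) and to -0.02 when libraries were scaled to the same total (adjusted p = 0.123), and went to 0.32 without DDC monosome replicate 2 (0.0983). Translation factors (22 higher, 5 lower of 50), splicing regulators (15 higher, 5 lower of 44), replication genes (17 higher, 0 lower of 36), NRF2 genes (13 higher, 0 lower of 31) and cytoskeleton genes (18 higher, 3 lower of 40) also passed. Of these 13 lists, noncoding RNAs alone passed with an estimated correlation (adjusted p = 0.0262, and 0.0594 to 0.779 for the others).

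Camera gave, in DDC, adjusted p = 6.23e-21 for proteasome, 1.66e-17 for oxidative phosphorylation, 7.46e-07 for fatty acid oxidation, 3.62e-06 for amino acid genes, 8.4e-07 for macrophage markers, and 0.00585 for mitosis. It gave adjusted p = 7.46e-07 for noncoding RNAs, 0.00524 for translation factors, 0.0368 for splicing, 8.71e-05 for replication, 0.000489 for NRF2 and 0.0404 for cytoskeleton. Estimating the correlation gave adjusted p = 0.0594, 0.345, 0.3, 0.487, 0.3, 0.487, 0.0262, 0.3, 0.566, 0.3, 0.364 and 0.487 in the same order. The calls of translation factors (adjusted p = 0.4), splicing (0.102), NRF2 (0.0601) and cytoskeleton genes (0.4) ended under quantile normalization. With equal totals the calls of NRF2, translation factor, mitosis, cytoskeleton and replication lists held at lower medians. These went from 0.71 to 0.13 for NRF2 genes, 0.64 to 0.10 for translation factors and 0.51 to 0.12 for mitosis genes. Cytoskeleton genes went from 0.92 to 0.37 and replication genes from 0.91 to 0.38. Without DDC heavy polysome replicate 2 the calls of translation factors (0.058), splicing (0.378) and cytoskeleton genes (0.236) ended. So did splicing without DDC monosome replicate 2 (0.0753) or with equal totals (0.109), and cytoskeleton genes without DDC monosome replicate 1 (0.0788). The amino acid median was 0.71 without DDC monosome replicate 2 and over 1.5 times that with it. Secreted plasma protein genes did not pass in DDC (2 higher and 2 lower of 36; median 0.40; adjusted p = 0.281), and Vtn (0.47, adjusted p = 0.256) and Serpinc1 (0.70, 0.135) were not called.

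In chow 2787 genes were higher and 2476 lower on heavy polysomes of 11771 tested, and in DDC 2139 and 1705 of 11770 (limma, Benjamini-Hochberg). Across 11758 genes the changes in the 2 diets had a correlation of 0.734. Here 1566 genes were higher in both (506 for independent lists), 1160 lower in both (359), and 33 were called in opposite directions. Scaling to equal totals moved the median of all genes by -0.37 in both diets and turned the balance of the calls, to 1291 higher and 3749 lower in chow and 956 and 3141 in DDC.

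The seventh comparison asked whether the diet changed the share of each message on heavy polysomes relative to cytoplasm. H19, an imprinted RNA that is not translated, rose with DDC in cytoplasm from 0.0312 to 29.6 FPKM and less on heavy polysomes, from 0 in both libraries to 1.54 (difference -3.51, adjusted p = 0.00997). In chow H19 was near 0 in both pools, so its share there could not be measured. Its difference is mostly that between the 2 DDC pools and does not show a changed share. Hmmr (chromosome 11, 40701395 to 40733422), a spindle protein gene, had a difference of -1.44 (adjusted p = 0.0488), whose call ended without CHOW cytoplasmic replicate 1 (adjusted p = 0.317) and without each of the other libraries compared except DDC heavy polysome replicate 2. The other 3 genes with a lower difference, named after their values were seen, were the adipokine gene Serpina12 (-2.21, adjusted p = 0.0221), Slfn9 (-1.73, 0.0221) and the predicted gene Gm9354 (-1.94, 0.0195). Higher differences were called for 7 genes, among them the RNA polymerase III subunit gene Polr3g (2.38, adjusted p = 0.027) and the histone gene Hist1h3g (1.5, 0.027). Of the 12 genes, Polr3g and Serpina12 had no group listed at 0 in both libraries. In all 12 genes of 11757 were called (limma, Benjamini-Hochberg), while 1390 had an unadjusted p under 0.05 where 588 are expected. In simulated data of this design 44 percent of 2 log2 unit differences were recovered.

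As lists, secreted plasma protein genes (34 genes, median difference -0.62), proteasome genes (37, -0.42), oxidative phosphorylation genes (75, -0.39), replication genes (36, -0.38) and cholesterol synthesis genes (24, -0.47) were lower on heavy polysomes relative to cytoplasm with DDC. Macrophage (24, 0.83), endothelial (18, 0.58) and stellate markers (23, 0.34), urea cycle and amino acid genes (37, 0.40) and ribosomal protein genes (79, 0.26) were higher. No member of these 10 lists was called over all genes. Over the list alone 1 macrophage marker was lower. By camera the adjusted p-values were 0.000561, 5.64e-05, 1.83e-05, 0.0217, 0.0252, 1.83e-05, 0.00221, 0.0446, 0.0244 and 0.0117 in the order given. None of the 10 passed with an estimated correlation (adjusted p = 0.822 for secreted proteins, 0.808 for proteasome and stellate markers, and 0.802 for macrophage and endothelial markers), and none passed fry. Under quantile normalization the oxidative phosphorylation median turned to 0.02 (adjusted p = 0.815) and the proteasome and stellate calls ended (-0.16, 0.116, and 0.10, 0.552). The medians of secreted proteins (-0.32), amino acid genes (0.73), replication (-0.64), ribosomal proteins (0.43) and macrophage markers (0.55) moved there too. With equal totals the cholesterol (-0.27, 0.057), oxidative phosphorylation (-0.09, 0.057) and stellate calls (0.04, 0.365) ended, and the medians were -0.32 for secreted proteins, 0.69 for amino acid genes, 0.56 for ribosomal proteins and -0.13 for proteasome genes. Without the 4 chow libraries of preparation 1 the proteasome, oxidative phosphorylation and macrophage calls alone were left, with replication at -0.15. The proteasome and macrophage calls held without each single library, and the other 8 did not. Without CHOW heavy polysome replicate 1 the calls of secreted protein (0.1), amino acid (0.1), cholesterol (-0.03, 0.533), replication (0.0536), ribosomal protein (0.1), endothelial (0.0536) and stellate lists (0.421) ended. Without DDC heavy polysome replicate 1 the amino acid median turned to -0.05 (0.813), and the replication (0.104) and ribosomal protein calls (0.474) ended. Without DDC heavy polysome replicate 2 the oxidative phosphorylation (-0.05, 0.448) and stellate calls (0.106) ended, while the amino acid median was 0.69 and the cholesterol median -0.27. The oxidative phosphorylation median was -0.70 without DDC heavy polysome replicate 1 and -0.25 without DDC cytoplasmic replicate 1, where the endothelial median was 0.36. The cholesterol median was -0.80 and -0.78 without CHOW cytoplasmic replicate 1 or CHOW heavy polysome replicate 2, and the replication median -0.62 without CHOW cytoplasmic replicate 2. In cytoplasm, the amino acid (0.0556) and replication calls (0.298) ended without CHOW replicate 1, and the cholesterol (0.595), ribosomal protein (0.15) and stellate calls (0.25) without CHOW replicate 2. The cholesterol (0.113), replication (0.144) and stellate calls (0.144) ended without DDC replicate 1, and the amino acid (0.171) and ribosomal protein calls (0.173) without DDC replicate 2. Cd68 (1.60, adjusted p = 0.269), Vtn (-1.43, 0.273), Mki67 (-1.85, 0.141) and Rps16 (0.89, 0.373) were not called.

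The eighth comparison asked whether the diet changed where a message sat between monosomes and heavy polysomes. Ribosomal protein messages were higher on heavy polysomes relative to monosomes in DDC than in chow, with the list's diet change called on monosomes (median -1.41) and not on heavy polysomes (0.23, adjusted p = 0.2). Rps3a1 (chromosome 3, 86137940 to 86142702) was at 302 ± 8.77 on heavy polysomes and 1417 ± 1.01 on monosomes in chow, and at 488 ± 104 and 352 ± 74.6 in DDC (difference 2.70, adjusted p = 0.0131). Rpl5 (chromosome 5, 107900502 to 107909005), which carries 5S RNA into the ribosome, had a difference of 2.45 (adjusted p = 0.0231), with Rpl23 at 2.37, Rps23 at 2.35, Rpl26 at 2.31, Rpl23a at 2.12 and Rpl22 at 1.81. The growth-regulated messages Tpt1 (chromosome 14, 75845093 to 75848525; 2.25, adjusted p = 0.0194) and Eef1b2, an elongation factor gene (1.86, 0.0252), lay the same way. Vtn lay the other way, at 10910 ± 2133 against 959 ± 124 in chow and 6611 ± 58.9 against 4779 ± 177 in DDC (difference -3.03, adjusted p = 0.0144). So did Serpinc1 (-2.70, adjusted p = 0.023), Serpinf1 (-2.44), the transporter gene Slc22a18 (chromosome 7, 143473736 to 143499334; -2.99) and Amy1 (chromosome 3, 113555710 to 113606699; -2.77). Tmem205 (chromosome 9, 21921008 to 21927556; -2.63, adjusted p = 0.0484) and the cytochrome P450 genes Cyp2d10 (-2.45) and Cyp2a12 (-1.54) lay with them. Each of these genes kept its direction but lost its call with array weights and without the 4 chow libraries of preparation 1 (Rps3a1 adjusted p = 0.0858, Vtn 0.119). With the fractions of each preparation as pairs Eef1b2 (0.0595) and Cyp2a12 (0.0609) were not called.

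Of 79 ribosomal protein genes 30 were higher and 0 lower in this difference (71 over the list alone; median 1.60), with paralogs and pseudogenes as a source of uncertain values. The median change from monosome to heavy polysome was -1.05 and -1.15 in the chow preparations and 0.49 and 0.79 in the DDC preparations. Of 35 secreted plasma protein genes tested 5 were lower and 0 higher (20 over the list alone, median -1.44), where the same medians were 2.02 and 1.58 in chow and 0.47 and 0.47 in DDC. Members of this list not tested were Alb and Trf, at 0 in all libraries, and Apoe, Ahsg, Apoa1, Apoa2 and Hpx, listed at 0 in a compared group. Camera and fry also left out Apoc1, C3 and Ttr, listed at 0 in groups outside this comparison. Cytochrome P450 genes (2 lower, 0 higher of 38; 5 over the list alone; median -0.75), macrophage markers (0 called of 24; 2 higher over the list alone; 0.88) and splicing regulators (0 of 44; 0.58) also passed. So did translation factors (2 higher of 50; 9 and 2 over the list alone; 0.30), mitosis genes (0 of 33; 5 and 1 over the list alone; 0.36), acute-phase genes (0 of 26; -0.75) and proteasome genes (0 of 37; -0.36). By camera the adjusted p-values were 2.95e-41 for ribosomal proteins, 2.76e-10 for secreted proteins, 0.000835, 0.000921, 0.00105, 0.0101, 0.021, 0.0233 and 0.0219 for the others in the order given. None of the 9 passed with an estimated correlation (adjusted p = 0.557 for ribosomal proteins, secreted proteins, cytochrome P450, macrophage, splicing and translation factors, 0.689 for mitosis, 0.733 for acute phase and proteasome). By contrast fry gave 0.0179 for ribosomal proteins, 0.0398 for translation factors and 0.0534 for secreted proteins. The proteasome, mitosis and acute-phase calls ended without the 4 chow libraries of preparation 1 (adjusted p = 0.259, 0.543 and 0.0786), as did translation factors (0.0786), and splicing ended without DDC heavy polysome replicate 2 (0.0957). Without DDC monosome replicate 2 or DDC heavy polysome replicate 1 the cytochrome P450 median was -1.29 and -1.302. The macrophage median was 0.47 without CHOW heavy polysome replicate 2 (adjusted p = 0.0429) and 0.42 under quantile normalization (0.0183). The mitosis call also ended without CHOW monosome replicate 1 (0.0676), DDC monosome replicate 2 (0.0541) or CHOW heavy polysome replicate 1 (0.25) and with equal totals (0.916), and translation factors without DDC heavy polysome replicate 2 (0.18, adjusted p = 0.0871), whose median was 0.55 without DDC heavy polysome replicate 1 (0.00133) and 0.47 with equal totals. The acute-phase call ended without CHOW or DDC monosome replicate 2 (0.123 and 0.282) and without CHOW or DDC heavy polysome replicate 1 (0.132 and 0.197). The proteasome call ended without CHOW monosome replicate 1 (0.158), DDC monosome replicate 2 (0.0541), CHOW heavy polysome replicate 1 or 2 (0.0545 and 0.0506) or DDC heavy polysome replicate 1 (0.28), and under quantile normalization (0.88) or equal totals (0.206).

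**Figure D3:**
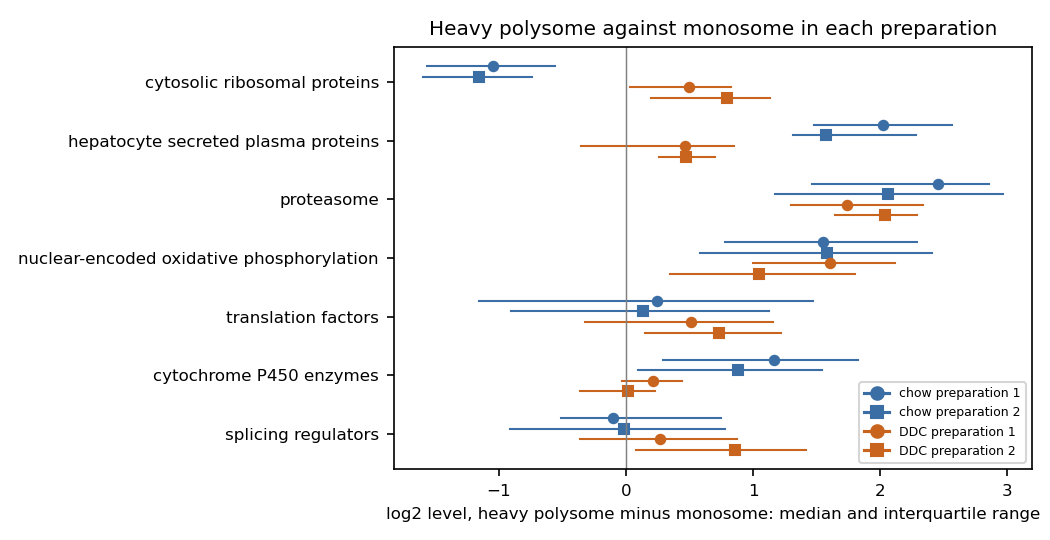
Change from monosome to heavy polysome (log2) of 7 gene lists in each preparation; points are list medians and lines the interquartile range. Ribosomal protein genes lie below 0 in both chow and above 0 in both DDC preparations (the DDC median turns below 0 under quantile normalization or equal totals), and proteasome genes lie above 0 in all 4.

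Over 11758 genes, 114 were higher and 103 lower in the difference (limma, Benjamini-Hochberg), 2381 had an unadjusted p under 0.05 where 588 are expected. A fit to the compared groups only called 1 gene, and array weights gave 4. Simulated differences of 2 log2 units were recovered in 49 percent of cases. The count moved to 36 without CHOW monosome replicate 2 and to 408 without CHOW monosome replicate 1. Atf4 (0.27, adjusted p = 0.731), Alas1 (-1.28, 0.239), Cyp7a1 (1.70, 0.304), Fech (0.46, 0.545), Ccnd1 (0.51, 0.813), Spp1 (0.51, 0.858) and Mki67 (-0.63, 0.373) were not called.

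Chow preparation 1 differed from the other libraries in genes of sex. Xist, expressed from the inactive X chromosome of females, was present in its 4 libraries (0.0394 to 2.45 FPKM) and at 0 in the other 12. The Y-linked gene Eif2s3y was at 0 in those 4, at 21.4 to 34.5 in chow preparation 2 and at 4.2 to 21 in DDC. The female-biased liver gene Cyp2b9 was at 184 to 547 in preparation 1 and 5.02 to 22.3 in preparation 2, and the male-biased gene Cyp4a12a at 0.0588 to 0.478 and 178 to 369. In DDC Cyp4a12a stood at 0 to 1.63 and Elovl3, another male-biased gene, at 0 to 0.0324. These genes moved alongside the Mup and Slco1a1 falls above, which are also under growth hormone control in liver.

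**Figure D4:**
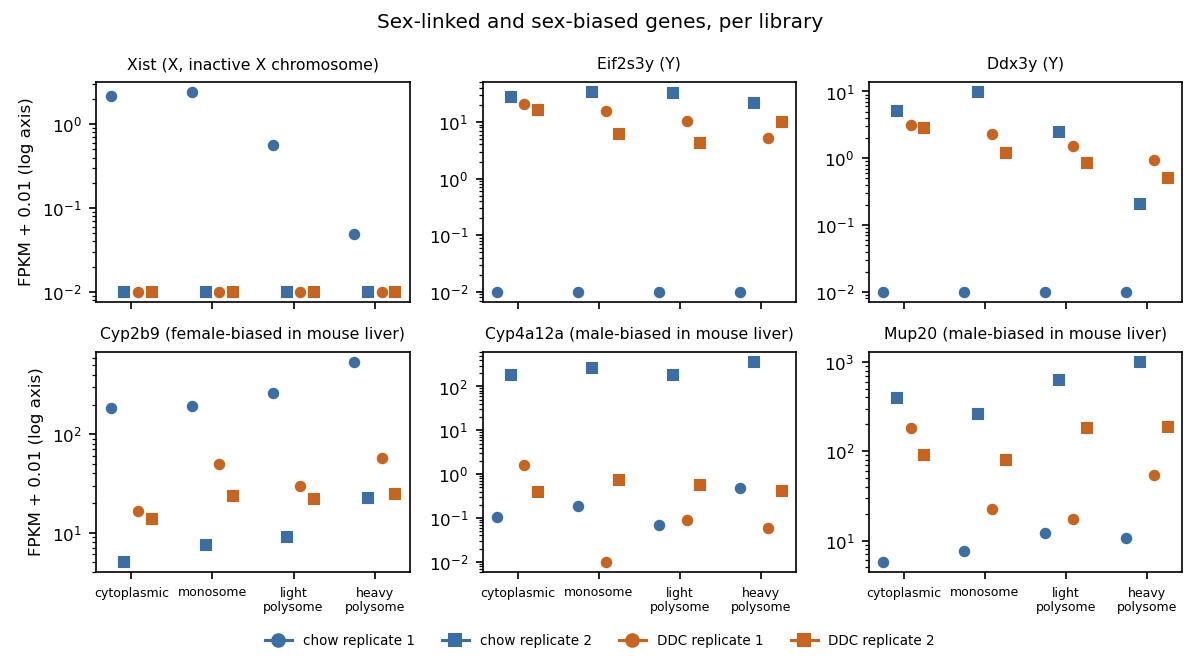
Expression of 6 sex-linked or sex-biased genes in the 16 libraries (FPKM + 0.01, log axis), with points as single libraries. Chow preparation 1 carries Xist and lacks Y-linked transcripts.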

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

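Each result here was listed because the change between fractions differed between chow and DDC by a tested interaction in limma or camera; of the tests below, that of lost membrane-bound polysomes and those without the 4 chow libraries of preparation 1 were chosen only after the result was seen, and the fits without CHOW monosome replicate 2, set in advance, were used as tests of that library only then.

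For heavy polysomes against cytoplasm 12 genes were called between the diets, among them Hmmr (-1.44). All of them but Polr3g and Serpina12 had a group listed at 0 in both libraries, and no call was left with such genes left out. The lists were secreted plasma proteins (-0.62), urea cycle and amino acid genes (0.40), cholesterol synthesis (-0.47), replication (-0.38), ribosomal proteins (0.26), oxidative phosphorylation (-0.39), proteasome (-0.42), and macrophage (0.83), endothelial (0.58) and stellate markers (0.34), each a median difference on the log2 scale that passed camera with the preset correlation and did not with an estimated correlation. For heavy polysomes against monosomes 217 genes differed. The lists were ribosomal proteins (1.60), secreted plasma proteins (-1.44), cytochrome P450 genes (-0.75), mitosis (0.36), translation factors (0.30), acute phase (-0.75), splicing regulators (0.58), proteasome (-0.36) and macrophage markers (0.88), none of which passed with an estimated correlation (adjusted p = 0.557 to 0.733). The named genes were Rps3a1 (2.70), Rpl5 (2.45), Rpl23 (2.37), Rps23 (2.35), Rpl26 (2.31), Rpl23a (2.12), Rpl22 (1.81), Tpt1 (2.25), Eef1b2 (1.86), Vtn (-3.03), Slc22a18 (-2.99), Amy1 (-2.77), Serpinc1 (-2.70), Tmem205 (-2.63), Serpinf1 (-2.44), Cyp2d10 (-2.45) and Cyp2a12 (-1.54).

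Ribosomal protein messages differed between the diets in their place between monosomes and heavy polysomes (median 1.60 over 79 genes). Short coding sequences shifting as a class were excluded as the whole cause: genes matched to 76 ribosomal protein genes on coding length and level had a median of -0.35, against 1.58 for those 76, and 100 percent of the latter lay above 0 against 34.2 percent. The library with the fewest genes under 10 fragments was excluded as well, since without CHOW monosome replicate 2 the median was 1.501 and the list still passed, and so was the other sex of chow preparation 1, since without its 4 libraries, which leaves 1 chow preparation, the median was 1.63 (adjusted p = 7.9e-21). A shift of 5' terminal pyrimidine messages as a class cannot be told apart from none: 95 other genes whose annotated 5' end begins with C and 4 pyrimidines lay 0.091 above matched genes (percentile 87.2 of the random sets), and the bound set in advance was wrong, because only 9 of 76 ribosomal protein genes, which are known to carry the motif, showed it at the annotated 5' end. What stays open is a growth-dependent control of these messages by the diet, a difference in cycloheximide run-off or gradient collection between preparations, and the correlation between genes of the list, with which camera did not call it (adjusted p = 0.557).

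Secreted plasma protein messages lay further towards monosomes in DDC (median -1.44 over the 35 genes tested). Camera with an estimated correlation (adjusted p = 0.557) and fry (0.0534), both run without Apoc1, C3 and Ttr, did not call it. A loss of membrane-bound polysomes from the DDC preparations would lower the list on polysomes with no gain on monosomes. The list rose on monosomes relative to cytoplasm (median 0.82, 29 of 35 genes above 0), which goes against that loss but is weak evidence. This median has no p-value, the genes are not independent, and DDC cytoplasm and DDC fractions carried different preparation names. CHOW monosome replicate 2 as the source was argued against by a median of -1.35 without it. The other sex of chow preparation 1 as the source was argued against by a median of -1.34 without its 4 libraries, which leaves 1 chow preparation (adjusted p = 6.15e-05). The shift was wider than the list: 660 other genes with an N-terminal hydrophobic segment lay -0.37 from matched genes (-0.57 against -0.20), below each of 10000 random sets, with the segment present in 28 of 31 secreted and 30 of 32 cytochrome P450 genes and in 0 of 76 ribosomal protein and 1 of 34 proteasome genes. A candidate explanation is therefore a change common to messages translated at the endoplasmic reticulum, which may be biological or technical. Apart from the weak check of lost membrane-bound polysomes, neither was tested.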

How the results depend on the processing

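Chosen after seeing the data were listed zeros kept as values, genes at 0 in a whole group left out, equal totals for the lists and the fit without the 4 chow libraries of preparation 1. Lists were run with camera at the preset correlation under TMM scaling, quantile normalization, equal totals, the replicate block, without each replicate and without the 4 chow libraries of preparation 1, and not under the other alternatives. Of the results of lists that passed, 967 kept direction and call there, 107 lost the call and 1 turned with a call. The estimated correlation, given below, is not among these. Of the named gene results over all alternatives but transcript values 8845 kept their status of called or not called, 88 gained a call, 453 lost it and 4 turned. Genes not called in either fit are among the 8845 whatever their direction. Counts called were 2629, 4353, 3541, 2915, 5263, 3844, 12 and 217 for the 8 comparisons in the order of the report, and each of those not given below stayed within 1.5 times. limma-voom was not run, because the values are FPKM and not counts. Where nothing else is said the cause was not tested.

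A filter at 50 FPKM in 2 libraries tests fewer genes and called 922, 1263, 1149, 1041, 1693 and 1320 for the first 6 comparisons, and 0 for heavy polysomes against cytoplasm, where limma had 1390 genes at an unadjusted p under 0.05 with the filter at 1 FPKM. Fits to the compared groups only called 4266 in cytoplasm, 1754 on monosomes, 362 on heavy polysomes, 2706 in the chow contrast, 633 in the DDC contrast, and 1 for each difference between diets. Array weights gave 5247 in cytoplasm, 1902 on heavy polysomes and 4 for heavy polysomes against monosomes by diet. Without the 4 chow libraries of preparation 1, with fewer samples, 969 genes were called in cytoplasm, 1820 on light and 1837 on heavy polysomes, 3060 in the chow contrast and 110 for heavy polysomes against monosomes by diet. Light polysomes in place of heavy ones gave 1503 in chow, 428 in DDC, and 7 and 4 for the differences between diets; Mir6236 in chow turned to -0.78, and in DDC Gpt turned to -0.14, Tm4sf4 to -0.15 and Aqp1 to -0.49. The difference between diets of heavy polysomes against cytoplasm, 12 genes, became 5 with pseudocount 0.5, 67 with pseudocount 5, 50 without a filter, 7 with quantile normalization, 33 with equal totals, 72 at transcript level, 25 with listed zeros kept, and 0 with genes at 0 in a whole group left out, which removes all of the 12 but Polr3g and Serpina12 by construction. That of heavy polysomes against monosomes, 217 genes, became 468 with pseudocount 5, 797 at transcript level and 142 with genes at 0 in a whole group left out.

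Leaving out each replicate in turn, where the lone sample left is assumed to vary like the other groups, gave 1190 to 1292 genes in cytoplasm, 2948 to 3862 on monosomes, 2014 to 2631 on light polysomes, 2056 to 2538 on heavy polysomes, 4266 to 4820 and 2825 to 3166 in the contrasts of chow and DDC, and 2 to 44 and 36 to 408 for the differences between diets. The cytoplasmic count was 1292 and 1190 without CHOW replicates 1 and 2 and 1265 and 1259 without DDC replicates 1 and 2, and the light polysome count was 2095 and 2014 without CHOW replicates 1 and 2. For heavy polysomes against cytoplasm by diet it was 44 without DDC heavy polysome replicate 2, 3 without DDC heavy polysome replicate 1, 3 and 6 without CHOW heavy polysome replicates 1 and 2, 2 and 3 without CHOW cytoplasmic replicates 1 and 2, and 4 and 5 without DDC cytoplasmic replicates 1 and 2. For heavy polysomes against monosomes by diet it was 408 and 36 without CHOW monosome replicates 1 and 2, 135 without CHOW heavy polysome replicate 1 and 142 without DDC heavy polysome replicate 2. Lists that passed numbered 3 to 12 and 6 to 11 for these differences, with 3 without CHOW heavy polysome replicate 1. With a replicate block counts were 2131, 3917, 3118, 2546, 5344, 3940, 8 and 193. It pairs preparations for heavy polysomes against monosomes, where Cyp2a12 (adjusted p = 0.0609) and Eef1b2 (0.0595) lost calls and Ccnd1 in chow and Orm2 in DDC gained them, but the diets, and DDC cytoplasm and fractions, by number alone, where Fau in cytoplasm (0.0586) and Hmmr (0.0848) did.

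With an estimated correlation camera passed 3, 1, 3, 5, 1, 1, 0 and 0 lists in place of 15, 16, 19, 17, 12, 13, 10 and 9, since it allows for genes of a list moving together, and fry passed 0 and 2 for the 2 differences between diets. Without the 4 chow libraries of preparation 1 these 2 had 3 and 5 lists. Ribosomal protein genes in DDC turned from 0.59 to -0.11 under quantile normalization. Scaling to equal totals moved the median of all genes by 0.17, 0.25, 0.23 and 0.28 in the diet comparisons, -0.37 in both contrasts and 0.11 for heavy polysomes against cytoplasm by diet, and 71 to 81.6 percent of diet calls were then higher with DDC and 25.6 and 23.3 percent of contrast calls higher on heavy polysomes, against 55.2 to 56.9, 53 and 55.6 percent in the deposited scaling. Depth limits genes with under 10 fragments, which were 15.3 to 24.5 percent of the single-transcript genes above 0 on heavy polysomes and 31.4 to 33.6 percent in cytoplasm.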

Other observations

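The handling of genes listed at 0 and, for chow preparation 1, the tests of sex as the source of the diet differences and of the differences in male-biased genes were chosen only after the values had been seen. Several abundant liver genes were listed at 0 in both libraries of a group while above 100 FPKM in another. Apoa1, the main protein of high-density lipoprotein, was at 6673, 10316, 11309 and 6407 FPKM in the 4 cytoplasmic libraries and at 0 in all heavy polysome libraries and in the DDC monosome and light polysome libraries. Haptoglobin (Hp) was at 872 and 1288 FPKM in chow cytoplasm, 6708 and 5010 on chow heavy polysomes, and at 0 in all 8 DDC libraries. By group 12, 9, 11 and 16 genes were so listed in chow cytoplasm, monosomes, light and heavy polysomes, and 17, 16, 13 and 14 in DDC. Trem2, a receptor of lipid-associated macrophages, was at 170 and 71.3 FPKM on DDC heavy polysomes and listed at 0 on those of chow. It was at 0 to 0.518 FPKM in the other chow libraries, so its 0 may be a low level.

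Among 7 mitochondrially encoded messages tested between heavy polysomes and monosomes 2 were higher and 5 lower in each diet, with medians of -3.42 in chow and -3.27 in DDC. The list did not pass camera (adjusted p = 0.902 and 0.845). Camera left out members listed at 0 in any group, such as mt-Nd5 and mt-Nd6. Its p-values therefore do not cover all of the 7 messages behind these medians. Malat1, a nuclear RNA, was at 4.54 ± 0.568 FPKM in DDC cytoplasm and 3.67 ± 2.1 in chow cytoplasm.

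Chow preparation 1 lay apart in sex-linked genes, with Xist in its 4 libraries only and Y-linked transcripts at 0. Wrong diet labels were excluded: over genes changed by the diet without these libraries, their highest median position between chow preparation 2 (0) and DDC (1) was 0.206, on heavy polysomes (interquartile range 0 to 0.498). Mice of the other sex fit, since Kdm6a, Kdm5c and Ddx3x, X-linked genes that escape silencing, were higher than in chow preparation 2 by a median of 0.36, in 10 of 12 pairs. Sex as the sole source of the diet differences was excluded, since without the 4 libraries, which leaves 1 chow cytoplasmic library assumed to vary like the other groups, 3062 genes had an unadjusted p under 0.05 in cytoplasm where 588 are expected. The mix of animals in the chow group was also weighed as the source of the diet differences in the male-biased genes Cyp4a12a, Elovl3, Hsd3b5 and Mup20. The bounds set for this test did not decide it, with DDC below both chow preparations in 9 of 16 pairs of gene and fraction. In Mup20 DDC lay above preparation 1 in each fraction (17.6 to 188 FPKM in DDC against 5.76 to 12.1). Preparation 2 carried Y-linked transcripts, as DDC did, and DDC lay below it in 16 of 16 pairs (median -6.21 on the log2 scale). A mix of sexes in chow would not lower DDC against preparation 2. These values therefore argue against the mix as the source of the falls in these genes, although 1 chow preparation was compared and the labels used here give no sex.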
